A study of Homo sapiens with 6 samples.

How the data were processed

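RNA sequencing of RKO, an established human colorectal cancer cell line, was compared between cells carrying a control short hairpin RNA (shControl, 3 libraries) and cells carrying a hairpin against TRMT6 (shTRMT6, 3 libraries). Per the labels' protocols, total RNA was extracted with TRIzol, and enriched mRNA was fragmented and made into cDNA libraries with a NEBNext Ultra kit; how the mRNA was enriched, the strand setting and the hairpin sequences were not given in the sources used here. Group and replicate number came from the sample titles. The table's column names abbreviate the groups differently from the titles, and each column was matched to the sample of its group and replicate number. Nothing in the labels says whether the 3 replicates of a group were separate cultures, so p-values measure the spread between these libraries, which may be technical.

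The deposited table gives 1 FPKM value (fragments scaled to gene length and library size) per gene and library, per the file headers. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM, without their roles; the genome build and annotation were not given in the sources used here. The table holds 20289 genes by Ensembl identifier, of which 5274 were listed at 0 in all 6 libraries. Symbols came from a table of gene names for 20257 identifiers and from GENCODE release 29 for 30 more. Coordinates, transcript length and GC content came from GENCODE release 29 by identifier (20171 genes found), so they are on that annotation's build and not necessarily on the one the authors used.

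FPKM values are not counts, so no count model was used. The depth of each library was estimated from the smallest steps between low values of genes with a single annotated transcript of at most 1000 bases, since FPKM times length is then a multiple of what 1 fragment is worth. The estimates were 20.7, 27.4 and 28.4 M fragments (mega) for shControl replicates 1, 2 and 3, and 20.6, 18.4 and 19.8 M for shTRMT6 replicates 1, 2 and 3. They assume the lengths of GENCODE release 29 and are rough: the bootstrap interval of shControl replicate 2 ran from 20.6 to 28.8 M (95%, 1000 resamples).

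Genes with a mean of at least 1 FPKM over the 6 libraries were tested (10592 genes). The test was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with a trended variance prior, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes; ratios of mean FPKM are given beside them. Every adjusted p of a single gene below is from this limma model. For TRMT6 an exact two-sided permutation test of the log2 values was added, which with 3 libraries against 3 cannot give a p under 0.1. All tests, gene lists, thresholds and the rule for named genes were fixed before the data were examined, except those described as chosen afterwards.

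The 36 gene lists covered histones and their processing factors, tRNA modification, translation, the cell cycle, DNA repair, p53 and other signalling pathways, stress responses, metabolism and markers of cell types. Lists with at least 5 tested members (34 lists) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, with a threshold of 0.05. Camera with an estimated correlation, and fry, were run as alternatives. The named genes were TRMT6 and TRMT61A; the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold whose groups did not overlap; up to 4 members past the threshold with the largest absolute log2 fold change from each called list; and up to 2 from every other list, or the 2 with the highest mean where none passed. Some genes that meet this rule are not used here. Genes named outside this rule are said to have been chosen after their values were seen.

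The groups share replicate numbers, so it was checked whether the numbers pair the libraries. The correlations across genes of the deviations from the group mean between libraries of the same number were 0.21, 0.36 and 0.17 for replicates 1, 2 and 3; the correlations between different numbers ran from -0.29 to 0.094. Deviations from a group mean cancel within the group, so these correlations are not independent and are weak evidence of pairing. The labels do not say what a number stands for. The main results come from the unblocked fit, and the fit with a replicate block was an alternative. Libraries of the same number are called pairs below. Other alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, other variance priors, other thresholds, and each library left out in turn. A correction that removes each library's smooth trend on transcript GC content, alone and with the replicate block, was added after the data were examined.

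The model was tested on simulated data for the comparison of shTRMT6 with shControl (10592 genes, the real means and spreads). Of 50 genes changed by 1.5-fold it recovered 29, of 50 changed by 2-fold 47, and of 50 changed by 3-fold and 50 changed by 4-fold all 50 each; of its 208 calls 17 more were members of the shifted list and 15 were false. Camera called the simulated list that had been shifted and none of 33 lists that had not. The simulated genes varied independently of each other, so this does not test camera on lists whose genes are correlated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Hairpin target sites were not analysed here because no hairpin sequence was at hand.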

Results

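Gene expression was measured by RNA sequencing in RKO cells, a human colorectal cancer line, with a control hairpin (shControl, n = 3 libraries) or a hairpin against TRMT6 (shTRMT6, n = 3). TRMT6 is the non-catalytic partner of TRMT61A in the enzyme that methylates adenosine in the T-loop of tRNAs. The single comparison asks which mRNAs change when TRMT6 is knocked down, and the study's title names histone synthesis. Estimated depth was 20.7 to 28.4 M (mega) fragments in the shControl libraries and 18.4 to 20.6 M in the shTRMT6 libraries.

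TRMT6 (ENSG00000089195; chromosome 20, bases 5937235 to 5950558 on the minus strand in GENCODE release 29) was lower in all 3 shTRMT6 libraries. Its mean was 16.4 ± 1.81 FPKM (SD, n = 3) in shControl and 1.47 ± 0.335 FPKM (SD, n = 3) in shTRMT6, 11.2-fold lower. Single libraries read 14.43, 17.96 and 16.85 FPKM in shControl and 1.58, 1.73 and 1.09 FPKM in shTRMT6. The log2 fold change was -2.82 (SE 0.13, limma adjusted p = 4.33e-08); the exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. The mRNA of its partner TRMT61A averaged 9.95 ± 1.41 and 11.3 ± 1.22 FPKM, a difference that did not pass the test (log2 fold change 0.17, SE 0.12, adjusted p = 0.294); it passed only with the GC correction added after the data were examined (0.33, adjusted p = 0.00792, and 0.0047 with the replicate block as well). Among 15 tested writers, erasers and readers of 1-methyladenosine, 3 rose and TRMT6 alone fell, and the list was not called (adjusted p = 0.288). TRMT10C, a subunit of the mitochondrial tRNA methyltransferase and RNase P, rose 1.78-fold (log2 fold change 0.80, SE 0.12, adjusted p = 0.000344).

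Of the 10592 genes tested, 3746 (35.4%) passed the threshold, 2042 higher and 1704 lower in shTRMT6. Most changes were small: 80 genes were higher and 41 lower by at least 2-fold. The groups did not overlap for 5117 genes (48.3%), where chance gives 10%. Correlations of log2 values were 0.9893 to 0.9947 within groups and 0.963 to 0.9818 between them, and the first principal component (67.6% of the variance) separated the groups. The count of changed genes was 2465 without shTRMT6 replicate 1 and 2407 without shTRMT6 replicate 2. Fold changes fell with the GC content of the transcript (Pearson r = -0.39 across genes, which are not independent replicates), in part through shControl replicate 1, without which r was -0.23. Per 10 points of GC, that library's deviation from the mean of all 6 rose by 0.22 in log2, against 0.0337 and -0.0046 in the other controls and -0.15 to -0.025 in shTRMT6; the groups differed by 0.17, and by 0.098 without it. The median log2 fold change was 0.27 in the tenth of genes with the lowest GC content and -0.14 in the tenth with the highest.

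Histone genes made up 8 of the 10 genes with the highest fold: HIST2H2AA3, H2BC5, H2BC12, H2AC6, HIST2H2AA4, H4C14, H2BC21 and H4C8. The other 2 were AOX1, an aldehyde oxidase, which rose from 1.2 ± 0.227 to 7.7 ± 1.01 FPKM (log2 fold change 1.98, SE 0.13, adjusted p = 9.13e-07), and RRM2B, the p53-induced subunit of ribonucleotide reductase. Among the lowest besides TRMT6 was DEGS1, the desaturase of the last step of ceramide synthesis. DEGS1 fell from 114.5 ± 14.7 to 28.3 ± 3.11 FPKM (4.04-fold, log2 fold change -1.98, SE 0.12, adjusted p = 3.47e-07). EMP1, MAP1LC3C (an LC3 family member of autophagy), GALNT6 (a mucin-type glycosyltransferase), GFPT2 (of the hexosamine pathway), CNTNAP1 and LGALS3BP were also among them, with log2 fold changes from -1.56 to -1.31. The annotated 3' UTRs of DEGS1 and EMP1 hold AGCTATA or CAGCTAT, 7-base words that also occur in the TRMT6 mRNA. The same holds for ESPL1, GINS1, ICAM1, EIF4H and H3-3B among the lower genes named here, and for MDM2, NT5E, HSPA4L, UTP15, FBXO32, CCNG2 and PIK3R3 among the higher ones. Whether the named genes hold these words more often than others was not tested. Of 10491 tested genes with an annotated 3' UTR, 8740 hold neither word, and 12.7% of all 7-base words occur in the TRMT6 mRNA.

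The set test called 15 of the 34 lists tested, 10 of them higher and 5 lower in shTRMT6. None of the 15 was called with an estimated correlation between genes, and another grouping of the same 6 libraries also called 15 lists; 11 of the 15 had a lower adjusted p in another grouping. The plot of all lists shows their medians and quartiles.

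**Figure D1:**
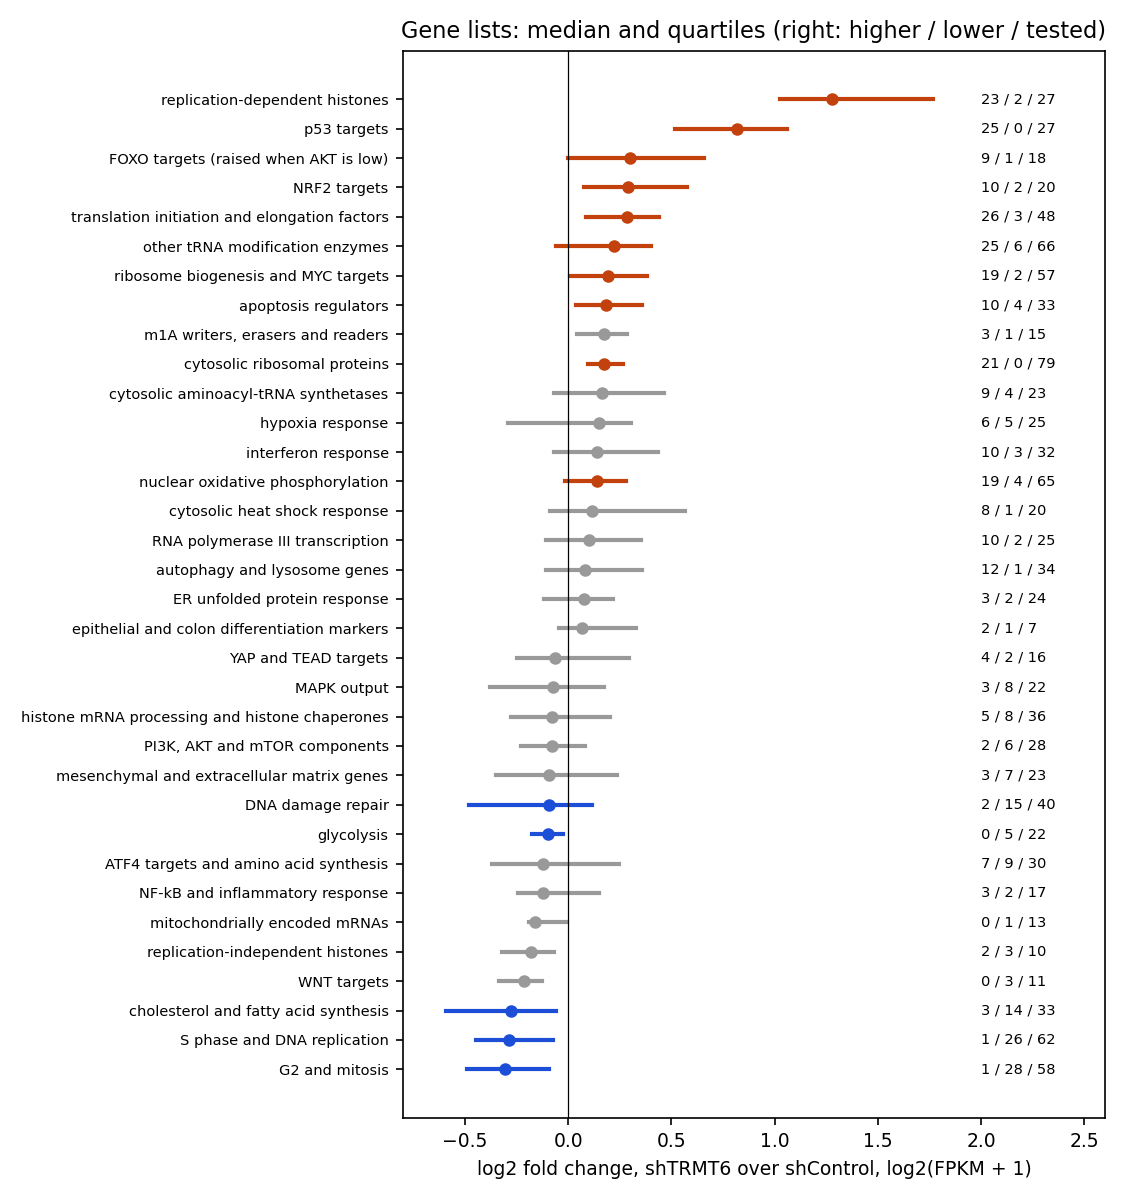
Median (point) and quartiles (line) of the log2 fold change on the log2(FPKM + 1) scale, shTRMT6 over shControl, for each of the 34 tested gene lists; red lists were called higher, blue lists lower and grey lists were not called. Numbers at the right give the members that were higher, lower and tested. Replication-dependent histones (median 1.28) and p53 targets (median 0.82) lie farthest to the right, and G2 and mitosis genes (median -0.30) farthest to the left.

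Replication-dependent histones, whose mRNAs are made mainly in S phase, rose as a group. Of 71 such genes, 27 reached the level for testing; 23 rose, 2 fell and 2 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 1.28 (2.42-fold) and the set test gave an adjusted p of 8.71e-15, or adjusted p = 0.155 with an estimated correlation. H2BC5 rose from 2.21 ± 0.256 to 22.0 ± 0.499 FPKM (9.97-fold, log2 fold change 2.85, SE 0.11, adjusted p = 9.61e-09). H2BC12 rose from 20.5 ± 2.16 to 133.3 ± 13.3 FPKM (6.50-fold, 2.64, SE 0.11, adjusted p = 9.7e-09), and H2AC6 from 4.75 ± 0.685 to 24.9 ± 3.73 FPKM (5.24-fold, 2.17, SE 0.13, adjusted p = 5.38e-07). HIST2H2AA3 and HIST2H2AA4 are near-identical copies, so the division of fragments between them is uncertain. HIST2H2AA4 rose 4.02-fold; HIST2H2AA3, listed at 0 in 1 shControl library, had a log2 fold change of 3.09 with an SE of 0.69, and its call ended with a robust variance prior (adjusted p = 0.125) and without a filter on low values (adjusted p = 0.0664). H4C14 and H2BC12 also share 96.2% and 50.5% of their 75-base windows with other genes. The 2 members that fell, H4C11 (log2 fold change -0.59) and H2AC20 (-0.51), were chosen after their values were seen; they share 79.6% and 23.7% of their windows with other genes, and with the GC correction no member fell. Without the 11 tested members that share over 10% of their windows, 15 of the 16 left rose and none fell.

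Other histone genes did not move with them. Of 10 tested replication-independent histones 2 rose and 3 fell (adjusted p = 0.182). H3-3B, which encodes the replacement histone H3.3, fell from 333.8 ± 7.8 to 210 ± 15.2 FPKM (log2 fold change -0.67, SE 0.09, adjusted p = 0.000195), and MACROH2A2 rose 1.52-fold. Of 36 histone mRNA processing factors and chaperones 5 rose and 8 fell (10 adjusted over the list alone), among the latter the chaperone ASF1B (1.81-fold) and TONSL (1.68-fold). This list was not called (adjusted p = 0.114), except with the GC correction (lower, adjusted p = 0.0275, and 0.0314 with the replicate block as well), and then not with an estimated correlation (0.541 and 0.431).

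**Figure D2:**
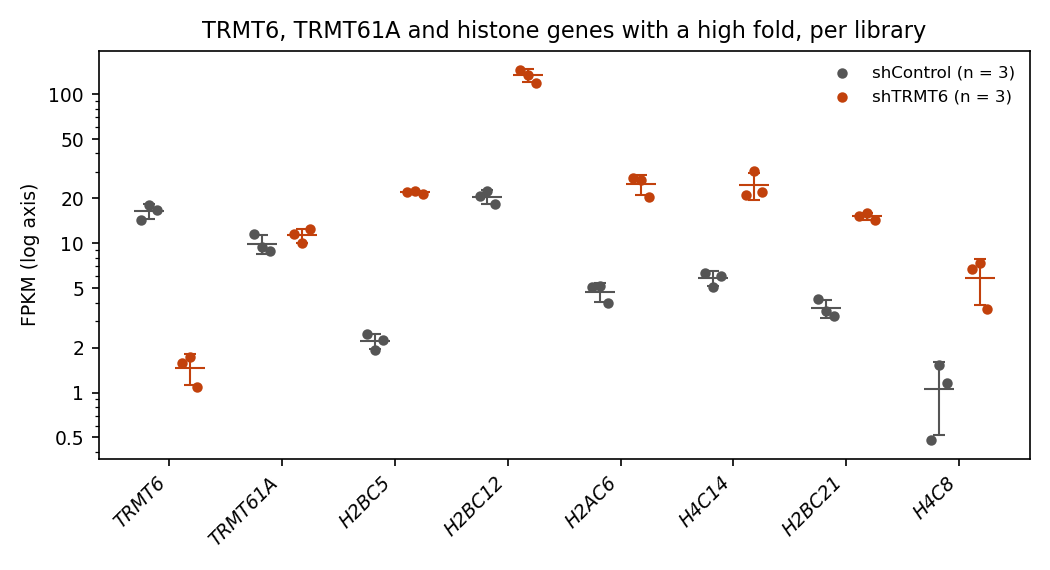
FPKM on a log axis in each library (points) with the group mean and SD (bars) for TRMT6, TRMT61A and the histone genes among the 10 highest folds, without HIST2H2AA3, listed at 0 in 1 library, and its near-identical copy HIST2H2AA4; H4C14 and H2BC12 share 96.2% and 50.5% of their sequence windows with other genes; shControl in grey, shTRMT6 in orange, n = 3 each. TRMT6 reads 1.09 to 1.73 FPKM in shTRMT6, and all 6 histone genes lie above their shControl libraries.

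Targets of the tumour suppressor p53 rose nearly throughout. Of 27 tested, 25 rose (26 adjusted over the list alone) and none fell, with a median log2 fold change of 0.82 (1.76-fold; set test adjusted p = 8.71e-15, or adjusted p = 0.105 with an estimated correlation). RRM2B rose from 9.53 ± 1.46 to 37.9 ± 3.41 FPKM (3.98-fold, log2 fold change 1.89, SE 0.12, adjusted p = 6.23e-07). The proapoptotic BBC3 rose 3.08-fold (1.45, SE 0.12, adjusted p = 5.33e-06), MDM2, the ubiquitin ligase of p53, 2.55-fold (1.33, SE 0.13, adjusted p = 2.7e-05), and the death receptor FAS 2.49-fold (1.21, SE 0.15, adjusted p = 0.000117). CDKN1A, the p53-induced cyclin-dependent kinase inhibitor, was chosen after its value was seen; it rose from 110.1 ± 14.5 to 210.1 ± 5.92 FPKM (1.91-fold, 0.93, SE 0.10, adjusted p = 5.33e-05).

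Apoptosis regulators, a list that shares BBC3, FAS, BAX and PMAIP1 with the p53 targets, also rose on balance: 10 of 33 were higher and 4 lower (median log2 fold change 0.18; adjusted p = 0.0261, or adjusted p = 0.521 with an estimated correlation). With the GC correction the median was 0.097, and 8 were higher and 4 lower. The members that moved act in both directions, since the inhibitors BCL2L1 and XIAP, chosen after their values were seen, rose too. Cytochrome c (CYCS) rose 2.10-fold. Among FOXO targets, which rise when AKT is low, 9 of 18 rose and 1 fell (adjusted p = 0.0174, or adjusted p = 0.521 with an estimated correlation). They included SESN1 (2.58-fold), the muscle-type ubiquitin ligase FBXO32 (2.32-fold), GABARAPL1 (1.83-fold) and CCNG2 (1.84-fold), of which SESN1 and CCNG2 are also in the list of p53 targets. The FOXO call ended without shControl replicate 1 (adjusted p = 0.0503; range over 18 alternatives 0.0094 to 0.0503).

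Many genes of DNA replication and mitosis fell. Of 62 S phase genes 26 fell (31 adjusted over the list alone) and 1 rose, with a median log2 fold change of -0.29 (adjusted p = 1.38e-07, or adjusted p = 0.521 with an estimated correlation). GINS1 of the replicative helicase fell 2.14-fold (log2 fold change -1.02, SE 0.10, adjusted p = 3.2e-05), POLD1, the catalytic subunit of DNA polymerase delta, 1.99-fold (-0.95, SE 0.11, adjusted p = 9.13e-05), and the helicase subunit MCM5 1.89-fold (-0.89, SE 0.11, adjusted p = 0.000147). Of 58 G2 and mitosis genes 28 fell (29 adjusted over the list alone) and 1 rose, with a median of -0.30 (adjusted p = 1.12e-07, or adjusted p = 0.521 with an estimated correlation). In this list 45 fell and none rose after the GC correction (median -0.35). The proliferation marker MKI67 fell from 31.1 ± 6.59 to 13.5 ± 0.945 FPKM (2.30-fold, -1.13, SE 0.14, adjusted p = 0.000102) and separase, ESPL1, from 19.1 ± 0.546 to 8.85 ± 0.367 FPKM (2.16-fold, -1.03, SE 0.10, adjusted p = 2.7e-05). PSRC1 and CDCA3 fell 1.74-fold and 1.73-fold.

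DNA damage repair genes, which share LIG1 with the S phase list, were also lower on balance. Of 40 tested, 15 fell and 2 rose (3 adjusted over the list alone), with a median log2 fold change of -0.094 (adjusted p = 0.0174, or adjusted p = 0.622 with an estimated correlation). With the GC correction the median was -0.24, and 20 fell and 2 rose. XRCC3, FANCG and RAD54L, which act in recombination or in crosslink repair, fell 1.83-fold, 1.81-fold and 1.78-fold. The call ended without shControl replicate 2 (adjusted p = 0.0507), without shTRMT6 replicate 3 (0.0849) and by fry (0.0732); over 18 alternatives the adjusted p ranged from 0.000169 to 0.0849.

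**Figure D3:**
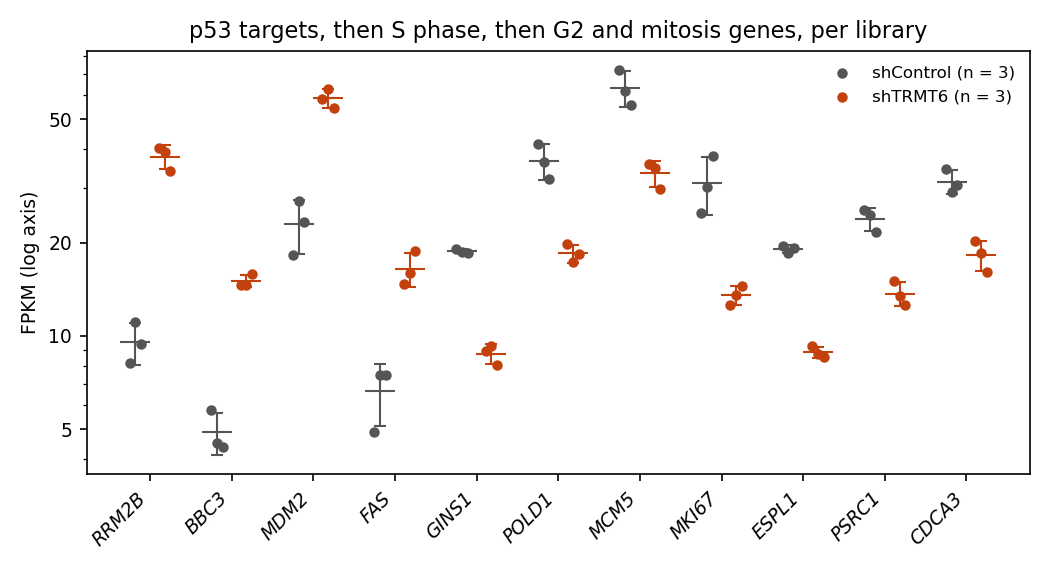
FPKM on a log axis in each library (points) with the group mean and SD (bars) for the named p53 targets (RRM2B to FAS), S phase genes (GINS1 to MCM5) and G2 and mitosis genes (MKI67 to CDCA3); shControl in grey, shTRMT6 in orange, n = 3 each. The groups do not overlap for any of the 11 genes: the first 4 are higher in shTRMT6 and the rest lower.

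Part of the genes of the translation machinery rose, by small amounts. Of 79 cytosolic ribosomal protein genes 21 rose and none fell, with a median log2 fold change of 0.17 (1.13-fold; adjusted p = 3.04e-05, or adjusted p = 0.521 with an estimated correlation). After the GC correction 38 rose and none fell (median 0.21). RPL23A rose 1.58-fold, RPL5 1.51-fold and RPS27A 1.38-fold. Of 48 translation initiation and elongation factors 26 rose and 3 fell (median 0.28; adjusted p = 0.000266, or adjusted p = 0.592 with an estimated correlation); with the GC correction the median was 0.16, and 21 rose and 3 fell. EIF3E, EIF3M and the release factor ETF1 rose by 1.56-fold to 1.61-fold, while EIF4H, a cofactor of the helicase EIF4A, fell from 171.9 ± 2.25 to 78.7 ± 4.5 FPKM (2.18-fold, log2 fold change -1.12, SE 0.09, adjusted p = 4.73e-06). Of 57 ribosome biogenesis genes and MYC targets 19 rose (20 adjusted over the list alone) and 2 fell (adjusted p = 0.00238, or adjusted p = 0.592 with an estimated correlation). They included UTP15 (1.99-fold), NOLC1 (1.87-fold), the RNA polymerase I factor RRN3 (1.85-fold) and WDR75 (1.82-fold).

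Enzymes of tRNA modification other than those of 1-methyladenosine were called higher, with 25 of 66 rising and 6 falling (median log2 fold change 0.22; adjusted p = 0.0409, or adjusted p = 0.592 with an estimated correlation). The GC correction lowered the median to 0.11, with 20 higher and 6 lower. TRMT11, a guanosine methyltransferase subunit, rose 1.86-fold, DUS4L, a dihydrouridine synthase, 1.97-fold and TRMT5 1.72-fold, and the deaminase subunit ADAT3 fell 2.01-fold. The TRMT5 call ended without a filter on low values (adjusted p = 0.0649). The list's call ended with a mean of at least 5 FPKM (adjusted p = 0.058), without shControl replicate 3 (0.0768), and without shTRMT6 replicate 1 (0.0552) or 2 (0.0582); the range over 18 alternatives was 0.0175 to 0.0768. Cytosolic aminoacyl-tRNA synthetases were not called, with 9 of 23 higher and 4 lower (10 and 5 adjusted over the list alone; adjusted p = 0.132); RARS1 rose 1.71-fold. RNA polymerase III genes were not called either, with 10 of 25 higher and 2 lower (adjusted p = 0.176); GTF3C6 rose 1.74-fold and SSB, which binds new RNA polymerase III transcripts, 1.59-fold.

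Part of the genes of cholesterol and fatty acid synthesis fell. Of 33 tested, 14 fell and 3 rose (median log2 fold change -0.28; adjusted p = 0.000206, or adjusted p = 0.435 with an estimated correlation). The desaturase FADS2 fell from 26.3 ± 1.76 to 12.9 ± 2.9 FPKM (2.05-fold, limma SE 0.14 on the log2 scale, adjusted p = 0.000236), and DHCR7, of cholesterol synthesis, fell 1.65-fold. Of 20 targets of NRF2, the regulator of antioxidant genes, 10 rose (11 adjusted over the list alone) and 2 fell (adjusted p = 0.0119, or adjusted p = 0.521 with an estimated correlation). Ferritin light chain, FTL, rose from 2860 ± 335.3 to 5734 ± 344 FPKM (2.00-fold, 1.01, SE 0.10, adjusted p = 3.78e-05), OSGIN1 1.89-fold and heme oxygenase HMOX1 1.59-fold, and the transporter ABCC1 fell 1.61-fold.

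Nuclear genes of oxidative phosphorylation were called higher, with 19 of 65 rising and 4 falling (median log2 fold change 0.14; adjusted p = 0.0491, or adjusted p = 0.622 with an estimated correlation). The largest changes in this list went both ways: CYCS rose, whereas UQCRC2 of complex III fell 2.07-fold (-1.03, SE 0.10, adjusted p = 1.78e-05), ATP5MC1 of ATP synthase 1.82-fold and NDUFB1 of complex I 1.71-fold. The call ended with median-of-ratios scaling (adjusted p = 0.0826), without a variance trend (0.0776), without shControl replicate 2 (0.0916) or 3 (0.143), and without shTRMT6 replicate 1 (0.0834) or 2 (0.0668); the range over 18 alternatives was 0.0072 to 0.143. Glycolysis genes were called lower (5 of 22 fell, none rose; adjusted p = 0.0491, or adjusted p = 0.592 with an estimated correlation). The lactate transporter SLC16A3, PFKFB4, hexokinase HK1 and ENO2 fell by 1.36-fold to 1.46-fold. The glycolysis call ended in 9 of the 18 alternatives, with adjusted p from 0.0222 to 0.369, the highest with the GC correction, when the list's median moved from -0.098 to -0.022. Of 13 mitochondrially encoded mRNAs only MT-ND3 passed, 1.38-fold lower (adjusted p = 0.0134; 0.0893 without a filter on low values and 0.0522 without shTRMT6 replicate 1). After the GC correction 8 of the 13 were lower and none higher, and the median moved from -0.16 to -0.26. That list was not called (adjusted p = 0.154), except without shControl replicate 1 (lower, adjusted p = 0.0046) and with the GC correction (0.0125, and 0.00395 with the replicate block as well); with an estimated correlation added the GC-corrected adjusted p was 0.612, and 0.441 with the block.

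Several other stress and signalling lists were not called. Cytosolic heat shock genes had 8 of 20 higher and 1 lower (adjusted p = 0.0809), with HSPA4L (log2 fold change 1.24, SE 0.13) and HSP90AA1 (1.98-fold) higher; this list was called higher with the replicate block (adjusted p = 0.0238), the GC correction (0.0283), both (0.0222) and fry (0.0371), but not with an estimated correlation (adjusted p = 0.592, 0.419 with the block, 0.569 with the GC correction and 0.431 with both). ATF4 targets and amino acid synthesis genes had 7 of 30 higher and 9 lower (adjusted p = 0.176): GDF15, also a p53-responsive cytokine, rose 2.27-fold and the transporter SLC1A4 fell 2.24-fold. The unfolded protein response had 3 of 24 higher and 2 lower (adjusted p = 0.699), with HERPUD1 1.45-fold higher and DNAJC3 1.51-fold higher, the latter not without a filter on low values (adjusted p = 0.0693). Interferon response genes had 10 of 32 higher and 3 lower (adjusted p = 0.114; called higher with the GC correction, 0.0266, with the block as well, 0.0209, and by fry, 0.00194; with an estimated correlation 0.521, 0.344 with the GC correction and 0.428 with both), with IFI27 1.65-fold higher. Autophagy and lysosome genes had 12 of 34 higher and 1 lower (adjusted p = 0.154; called higher with the GC correction, 0.0275, with the block as well, 0.0314, and by fry, 0.0162; with an estimated correlation 0.521, 0.344 with the GC correction and 0.51 with both), with GABARAP 1.49-fold higher.

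MAPK output genes had 3 of 22 higher and 8 lower (adjusted p = 0.176; called lower by fry, 0.0284, but 0.521 with an estimated correlation), among them the growth factor HBEGF (2.09-fold lower) and the immediate early gene EGR1 (1.83-fold lower). WNT targets had 3 of 11 lower and none higher (adjusted p = 0.0846; called lower by fry, 0.00553, but 0.521 with an estimated correlation), with LEF1 1.49-fold and CCND1 1.38-fold lower. PI3K, AKT and mTOR components had 2 of 28 higher and 6 lower (adjusted p = 0.154), with PIK3R3 1.77-fold higher and TSC2 1.59-fold lower. YAP and TEAD targets had 4 of 16 higher and 2 lower (3 adjusted over the list alone; adjusted p = 0.957). Of these NT5E, the ecto-nucleotidase CD73, rose from 2.23 ± 0.269 to 8.68 ± 1.03 FPKM (log2 fold change 1.58, SE 0.13, adjusted p = 4.73e-06), and the receptor kinase AXL fell from 351.1 ± 38.4 to 164.4 ± 20.9 FPKM (-1.09, SE 0.11, adjusted p = 3.2e-05). Hypoxia genes had 6 of 25 higher and 5 lower (6 and 6 adjusted over the list alone; adjusted p = 0.764), with ANGPTL4 1.60-fold lower and MXI1 1.56-fold higher. NF-kB and inflammatory genes had 3 of 17 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.305); PLAU and ICAM1 fell 1.83-fold and 1.49-fold.

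Of the 4 lists of cell identity markers, the 2 that could be tested were not called. Only 7 of 34 epithelial and colon differentiation markers reached the level for testing; 2 rose and 1 fell (adjusted p = 0.599). KRT18 rose 1.57-fold; EPCAM, at 4.2 and 6.29 FPKM, passed the test (adjusted p = 0.0282) but not without a filter on low values (0.111), nor without shControl replicate 1 (0.086) or shTRMT6 replicate 2 (0.114) or 3 (0.0691). Of 23 mesenchymal and matrix genes 3 rose and 7 fell (adjusted p = 0.592), with MMP1 (from 0.683 to 2.92 FPKM) and ACTA2 (from 0.777 to 2.81 FPKM) higher at low levels. Fibroblast markers had 1 tested member of 16, C1R, which fell from 3.99 to 2.07 FPKM. Leukocyte and endothelial markers had 2 tested members of 23, of which CORO1A fell 1.34-fold (adjusted p = 0.0219; 0.0579 without a filter on low values, and 0.0744 and 0.0505 without shTRMT6 replicates 1 and 2).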

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

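The GC correction, and the tests that combine it, the replicate block and the estimated correlation, were chosen after seeing the data. TRMT6 was lower and past the threshold under each of the 17 alternatives, with log2 fold changes from -3.42 (pseudocount 0.1) to -2.82, and -2.91 to -2.71 with each library left out. The count of genes changed, 3746, became 121 with a 2-fold minimum and 2063 at an adjusted p under 0.01, both stricter by construction. Leaving out each library gave 2407 to 3618, the lowest without shTRMT6 replicates 2 and 1 (2407 and 2465), with fewer samples. The other alternatives gave 2941 (no filter, 15015 genes tested) to 5266. Of the 3746 calls, 70.9% held without a filter, 76.1% with the GC correction and 63.3% to 86.8% without each library, counted with the same direction. The scaling alternatives moved the median of all genes from 0.024 to -0.0013 and -0.0077, and the share of higher calls from 54.5% to 50.5% and 48.9%.

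With the replicate block, following the pairing of the numbers, 4954 genes changed (2702 higher, 2252 lower), including all 3746; 16 lists were called, cytosolic heat shock genes being added, and the block changed no other call of a list or named gene. With the block and the GC correction 5266 genes changed (2630 higher, 2636 lower) and 19 lists were called.

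Called lists numbered 12 to 14 with each library left out and 13 to 19 under the other alternatives, except that an estimated correlation left 0, and 0 with the block, 1 with the GC correction (p53 targets, adjusted p = 0.0256) and 0 with both. The histone set test kept its direction, with adjusted p from 7.8e-19 to 2.2e-12 without each library and 7.39e-18 to 0.000354 otherwise. With the estimated correlation the adjusted p was 0.155, with the GC correction added 0.129, with the block 0.249 and with both 0.275. The correlation estimated for this list in the main fit was 0.105, against the preset 0.01. How much of the rise in adjusted p came from that was not tested. Of the 15 called lists 10 kept their call in all 18 alternatives that use no estimated correlation; DNA damage repair, FOXO targets, glycolysis, nuclear oxidative phosphorylation and tRNA modification lost it in at least 1, for causes that were not tested, and 7 of the 19 lists not called were called in at least 1. No called list or named gene changed sign. Of the called genes named besides TRMT6, HIST2H2AA3, DNAJC3, EPCAM, CORO1A, MT-ND3 and TRMT5 lost their call in at least 1 of 17 alternatives. The others kept it wherever they were tested. The filter on low values left members with a mean below 1 FPKM, 44 of 71 histone genes among them, out of the main test. Whether the depth of 18.4 to 28.4 M fragments limits such genes was not tested.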

Other observations

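The gene families, the search for 3' UTR words, its adjustment for base composition, and the tests of the GC correction were chosen after the results were seen. Among 112 families of at least 10 tested genes that share a symbol stem, camera called 7. Mitochondrial ribosomal proteins of the large subunit (MRPL) rose, 18 of 49 higher and 1 lower (median log2 fold change 0.16, adjusted p = 0.0161, and 0.00131 with the GC correction). Of 10 genes with an MCM symbol 7 fell and none rose (median -0.43, camera adjusted p = 0.0177, and 0.0101 with the GC correction). The S phase list already holds MCM2 to MCM7 and MCM10, so this family largely recounts its genes. A symbol stem can also take in genes outside a protein family. Of 138 transmembrane proteins with a TMEM symbol 38 fell and 12 rose (median -0.15, adjusted p = 0.0161, and 0.0101 with the GC correction). Zinc finger genes with a ZNF symbol had 99 of 346 higher and 14 lower (median 0.19, adjusted p = 0.00643), and their median was 0.11 after the GC correction (adjusted p = 0.057). With an estimated correlation no family was called (adjusted p = 0.931 for each of these).

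The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. For changed genes the real split gave 3746 and the highest of the others 1; among the 4 splits that part all 3 pairs the others gave 0. For lists the real split gave 15, and so did the split of shControl replicate 1 with shTRMT6 replicates 2 and 3 against the rest, which also parts all 3 pairs, so that 2 of the 10 splits gave as many lists. Splits that part 1 pair gave 7 to 13 lists. Of the 15 called lists 4 had their lowest adjusted p in the real split: p53 targets, replication-dependent histones, apoptosis regulators and FOXO targets. Even so, p53 targets and replication-dependent histones were called in all 9 other splits, with adjusted p down to 1.36e-06 and 1.27e-06. The number of called lists therefore did not set the real split apart from the others. The other splits mix the groups and keep part of the knockdown contrast, so their calls give no null level. The counts of members that passed come from the same libraries and were not tested against the shares over all genes. Of all 10592 genes tested, 2042 were higher and 1704 lower.

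The first pattern is in the 3' UTRs: among 16384 words of 7 bases, tested in 10491 genes for the mean log2 fold change of the genes holding the word (adjusted for UTR length and GC content), the lowest z belonged to AGCTATA (-7.37, 986 genes) and CAGCTAT (-6.03, 1177 genes), followed by AGCTATT (-5.40) and GCTATAT (-5.10), which overlap them but are not in the TRMT6 mRNA. Joined, the first 2 make CAGCTATA, which occurs once in the TRMT6 mRNA, in coding exon 7 of 11 (chromosome 20, bases 5942762 to 5942769, minus strand), as do 3.46% of all 8-base words at least once; no shuffle of 1000 gave a z as low as that of AGCTATA. The z of AGCTATA was -5.70 to -7.79 in all 9 pairs of a shTRMT6 with a shControl library. These pairs re-use the libraries in which the word was picked, so they add no support. For a library against the rest of its group the z was -1.21 to 2.27. This argues against an outlying library, but not against variation that happens to follow the groups. With the frequencies of bases and base pairs of the 3' UTR added to the adjustment, the z of AGCTATA was -7.28. The lowest of any word in the shuffles of that adjustment was -5.02, which argues against base composition. The pattern was not confined to 3' UTRs. The 335 genes with AGCTATA elsewhere in the transcript, and neither 7-base word in the 3' UTR, also lay lower, with a z of -3.08. Genes with the 8-base word lay lower than genes with a 7-base word only (difference -0.06 in adjusted log2 fold change, one-sided permutation p = 0.00379), in words picked from the same data, so seed pairing of the hairpin with other mRNAs is a hypothesis for part of the lower genes. Of the genes named, the 8-base word is in the 3' UTRs of EIF4H and H3-3B, which fell, and of UTP15, which rose, so that no single gene is assigned; the shift is small, since the 285 genes with the 8-base word, the 1466 with a 7-base word only and those with neither had adjusted means of -0.11, -0.051 and 0.012 and unadjusted means of -0.0067, 0.0325 and 0.03, and 19.3%, 15.0% and 16.2% of them fell; the test would be a second hairpin with another seed.

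The second pattern is the rise of replication-dependent histone mRNAs. Reads shared between near-identical copies are argued against by the median log2 fold change of the 16 members without such copies, 1.41. GC content is argued against by the median after the GC correction, 1.40, with a set test adjusted p of 1.39e-13 (range over the alternatives 7.8e-19 to 0.275). Weaker selection of polyadenylated RNA in the shTRMT6 libraries stays open, since most histone mRNAs lack a poly(A) tail and the labels do not say how mRNA was enriched; libraries made by depletion of ribosomal RNA would test this. The 13 genes with a spliced or long annotated transcript had a mean log2 fold change of 1.57 and the 14 with a short one only 1.05, a difference of 0.52 (one-sided permutation p = 0.0716) that cannot be told apart from 0 and so decides neither for such a shift nor for polyadenylated histone transcripts.

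The third pattern is the rise of p53 targets with the fall of S phase and mitosis genes. GC content is argued against by the 96.3% of the 81 called members that stayed called in the same direction after the GC correction. Lower depth of the shTRMT6 libraries was checked only in the 17 p53 targets with a mean of at least 10 FPKM over the 6 libraries. Their median log2 fold change was 0.82, with 16 of them higher. That floor admits some genes through their shTRMT6 values, such as FAS (6.62 FPKM in shControl and 16.5 in shTRMT6). The check is therefore weak evidence against depth as the source of the rise. Depth was not checked for the fall of the S phase and mitosis genes. The 102 S phase and mitosis genes whose annotated 3' UTRs lack both AGCTATA and CAGCTAT had a median of -0.30, with 46 lower and 2 higher. These 102 genes were selected for lacking the words. Their values show only that the fall was not confined to the 18 members with a word. Matches in the coding sequence or to other words were not tested in the 102 genes. With only 1 knockdown derivative in the design, loss of TRMT6 cannot be told apart from an indirect effect of the hairpin or of the derivative; rescue with a TRMT6 mRNA that the hairpin cannot bind would test this.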
